A study of Danio rerio with 26 samples.

How the data were processed

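The series measured RNA in brains of male zebrafish (Danio rerio) exposed to rotenone, a plant-derived inhibitor of complex I of the mitochondrial respiratory chain. Its 26 libraries fall into 3 groups: 10 from 1 year old fish at 3.75 nM, 9 from 1 year old fish at 37.5 nM, and 7 from 3 year old fish at 37.5 nM. Every sample carries a rotenone label, so no untreated background was measured here. Each title gives its sample a zebrafish number of its own, and the labels say nothing of pooling. The p-values therefore measure the spread between these samples. The labels set 2 further limits. The 3 year fish carry the strain label AB JxTu Tg(flk:mCherry) and the 1 year fish AB JxTu, so age and line cannot be separated. The 3.75 nM libraries stand in a count table of their own, so concentration cannot be separated from table or time of preparation.

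Libraries were made with the Illumina TruSeq RNA kit v2, per the labels' protocols, a kit that does not mark the strand of the transcript. Reads of overlapping and antisense genes can therefore not be told apart. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4 were used with the genome build GRCz10, with no role or order named. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here, so values of near-identical paralogs (the mhc1, ifi44, btr, gzm, nitr and hemoglobin families among them) are uncertain. The deposited count tables hold whole-number read counts for 32105 Ensembl genes, not normalized, with library totals from 20.6 to 36.0 in units of 1000000 counts. In the smallest library, a CPM of 1 equals 20.6 counts. All 26 columns belong to samples of the series.

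Beside each count table, the authors deposited a table under the name RPKM, which was handled as a score without a fixed unit. Over 8219 genes with at least 300 counts in every library, the ratio of score to count in 1 library against another ought to be a single factor. In 23 of 25 libraries set against the first one it instead varied between genes, with a median SD of 0.35 and a median range of 2.02 on the log2 scale, and repeated every 50 rows. The deposited scores thus divide each gene by a factor that depends on its row, and their column sums followed the count totals (Pearson r = 0.966 across libraries). They were used only as an alternative for the age comparison.

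Gene symbols came from a table of Ensembl identifiers, which named 26269 of 32105 genes (81.8%). Many zebrafish genes there carry a human-style capital symbol without the letter that tells duplicated copies apart. Where 2 genes share a symbol, the identifier is given. Before the data were examined, 29 gene lists and 2 symbol patterns (ribosomal proteins and proteasome) were fixed, together with the tests and the rule for named genes. Of 1099 list symbols, 1016 were matched: 742 directly, 228 to a suffix-free symbol and 46 through a synonym in the RefSeq gene table of assembly GRCz12tu. This order of matching was not fixed beforehand. The named genes are, per comparison, the 10 largest increases and the 10 largest decreases among genes at adjusted p under 0.05, mean log2 CPM of at least 1 and a symbol that is not a clone name. Added to these were up to 3 members per list with the smallest adjusted p, where the list passed its test or at least 3 members passed. The most abundant gene of each library served as a technical check. Genes outside this rule are said to have been chosen after their values were seen.

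Both comparisons used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr, robust dispersion and Benjamini-Hochberg adjustment at 0.05. The age comparison set 3 year against 1 year fish at 37.5 nM (16 libraries). The dose comparison set 37.5 nM against 3.75 nM at 1 year (19 libraries). The 9 libraries of 1 year fish at 37.5 nM are in both comparisons, which are therefore not independent. No covariate was used. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of F, and CPM (counts per 1000000) are given as mean ± SD with TMM library sizes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 31 lists. Camera with an estimated correlation and the directional test fry were alternatives. List scores per library are means of log2 CPM with a prior count of 2. Alternatives with DESeq2 1.42.0, other filters, limma voom with quality weights, subsets of the libraries and single libraries left out are described at the end of the document. Permutation tests used SciPy 1.17.1 in Python 3.11.15, and figures matplotlib 3.10.9.

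The numbers in the sample titles fall into a lower and a higher run that cross all 3 groups. Within each run, each group holds its own block of neighbouring numbers, so the order of numbers cannot be separated from group. The labels do not say what separates the runs. They entered only as a possible batch, as a covariate or by fitting each run alone. In the age comparison the first run held 4 and 3 libraries and the second 5 and 4. In the dose comparison they held 4 and 5, and 5 and 5.

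The test was tested on simulated counts made from the means, library sizes and dispersions of each comparison. Per fold size 100 genes with log2 CPM of at least 1 were changed. Genes were drawn independently, without runs of title numbers or carried-over RNA, so the shares do not hold for less expressed genes or for such structure. For the age comparison (19740 genes), 64% of genes changed 1.5-fold and 85% of those changed 2-fold were recovered. For the dose comparison (19564 genes) these shares were 62% and 90%. Among the unchanged genes, 7 and 10 were called. No pair of libraries within a group was a duplicate: chi-square per degree of freedom lay between 13.5 and 70.8 over 102 pairs, where sampling noise alone gives about 1.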

Results

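The data are gene counts from 26 brains of male zebrafish kept with rotenone, which blocks complex I of the respiratory chain. Library totals, in units of 1000000 counts, averaged 26.7 ± 4.26 (SD, n = 10) in 1 year old fish at 3.75 nM, 27.0 ± 3.11 (n = 9) in 1 year old fish at 37.5 nM and 27.4 ± 5.49 (n = 7) in 3 year old fish at 37.5 nM. Between 23687 and 24851 genes had a count. MT-CO1, the mitochondrially encoded subunit 1 of cytochrome c oxidase, was the most abundant gene of every library. Mitochondrially encoded genes took 10.2% ± 1.41, 11.5% ± 1.33 and 10.6% ± 1.26 of counts in these groups. The series title names 2 age groups after rotenone, and the design implies a comparison of ages at 37.5 nM and of concentrations at 1 year.

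Brains of 3 year old fish carried more RNA of many immune genes than brains of 1 year old fish at the same concentration. Genes of antigen presentation were among them. The gene b2m, the light chain of MHC class I, went from 117.9 ± 20 to 281.3 ± 93.5 counts per 1000000 (CPM) (log2 fold change 1.25, SE 0.17). On the same scale cd74b, the MHC class II invariant chain, rose by 1.15 (SE 0.17) and mhc1uca, an MHC class I heavy chain, by 2.4 (SE 0.23). Some macrophage and T cell genes rose with them, among them lgals9l1, a galectin (1.81, SE 0.26), IRF8, a transcription factor of microglia (0.96, SE 0.16), and ZAP70, a kinase of the T cell receptor (1.34, SE 0.21). Each of these 6 genes was above the 1 year median in 7 of 7 fish. Fewer genes fell, among them BDNF, a neurotrophin, by 0.41 (SE 0.09), and tek, an endothelial receptor kinase, by 0.68 (SE 0.16).

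Of 19887 genes tested, 979 were higher and 570 lower at 3 years by edgeR's quasi-likelihood test at adjusted p under 0.05, and 404 of the higher and 66 of the lower genes changed at least 2-fold. In 150 genes the groups did not overlap, which chance gives in 0.0175% of genes, and 147 of these passed the test. All of it compares fish that differ in age and in strain label alike.

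The list of interferon and antigen presentation genes had the smallest camera p. Of its 43 measured genes 20 were higher, none lower and 23 did not pass, or 24 higher when adjusted over the list alone, with a median log2 fold change of 0.90 (camera adjusted p = 9.87e-23). With an estimated correlation the adjusted p was 0.0989, so this call was lost there, while the directional test fry gave an adjusted p of 0.00124. PSME1, a proteasome activator used for antigen processing, rose 1.19 (SE 0.15, adjusted p = 0.000537). The list score was above the 1 year median in 7 of 7 fish and differed by 0.86 across runs, 0.70 within the first run of title numbers and 0.98 within the second.

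Microglia and macrophage genes counted 18 higher and 25 not past the test of 43 (25 higher when adjusted over the list alone; median 0.58, camera adjusted p = 1.82e-13, but 0.171 with an estimated correlation). Lymphocyte and granulocyte genes counted 11 higher and 15 not past the test of 26 (12 when adjusted over the list alone; median 0.60, camera adjusted p = 1.96e-06, but 0.171 with an estimated correlation). Besides ZAP70, il7r, the interleukin 7 receptor (1.91, SE 0.32), and cd8a, a co-receptor of cytotoxic T cells (3.21, SE 0.57), led the second list. Expression of cd8a was low, at 0.196 ± 0.172 CPM at 1 year and 1.82 ± 1.31 CPM at 3 years. The list scores of both were above the 1 year median in 7 of 7 fish and differed by 0.53 and 0.64, with 0.51 and 0.30 in the first run and 0.55 and 0.90 in the second. Inflammation and complement genes counted 6 higher of 30 (8 when adjusted over the list alone; camera adjusted p = 0.00245, but 0.380 with an estimated correlation). The complement component 4 genes c4 and c4b rose 1.23 (SE 0.20) and 1.4 (SE 0.28), and nfkb1, a subunit of the transcription factor NF-kB, rose 0.64 (SE 0.16). The list score differed by 0.19 and 0.31 within the runs.

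**Figure D1:**
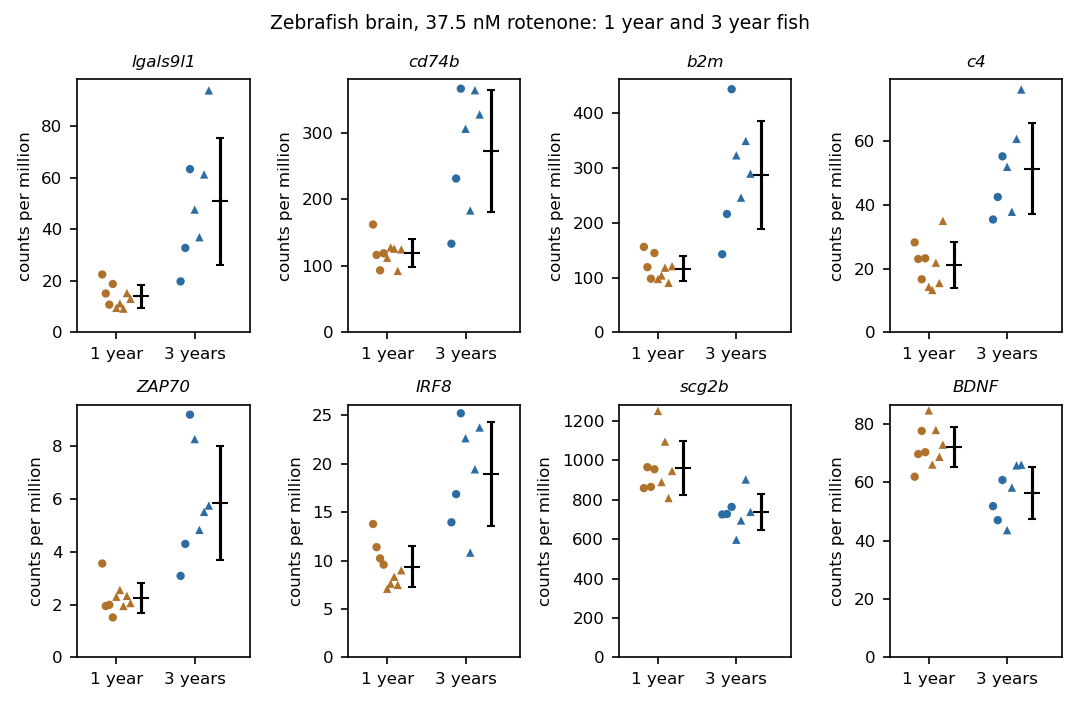
Counts per 1000000 of library total for 8 genes in each 1 year (n = 9) and 3 year (n = 7) fish at 37.5 nM, with circles for the first run of title numbers, triangles for the second, and mean ± SD beside the points. The immune genes lgals9l1, cd74b, b2m, c4, ZAP70 and IRF8 lay higher at 3 years, and the secretogranin gene scg2b and BDNF lower.

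The 10 largest increases were led by ifi44a6 (5.40, SE 0.81), of the interferon-induced 44 family, SERPINB1 (ENSDARG00000070396; 4.89, SE 0.54), an inhibitor of neutrophil proteases, myrfl (4.79, SE 1.03), related to myelin regulatory factor, the chemokine ccl34b.4 (4.33, SE 0.48) and btr23 (4.2, SE 0.56), of a tripartite motif family. The antiviral GTPase mxc (3.54, SE 0.69) and traf3ip2l (3.50, SE 0.71) followed. Among these increases, myrfl was above the 1 year median in 5 of 7 fish. SERPINB1 was tested in only 8 of 16 fits with 1 library left out. The genes s100s (3.60, SE 1.01) and LOXL2 (3.41, SE 0.92), a lysyl oxidase that cross-links collagen, were above the 1 year median in only 2 of 7 fish. The sodium pump subunit gene atp1a1a.4 (3.87, SE 1.03) was above it in 4 of 7. Leaving out replicate 6 of the 3 year fish took s100s to 0.67 and atp1a1a.4 to 1.81, and within the first run s100s stood at -0.20 and LOXL2 at -0.32. Of 16 fits with 1 library left out, the call was lost in 11 for s100s, 9 for atp1a1a.4 and 8 for LOXL2.

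Among the 10 largest decreases, the importin IPO8 went from 186 ± 12.2 to 51.8 ± 28.4 CPM (-1.84, SE 0.23) and SMAD1, which carries bone morphogenetic protein signals, from 106.7 ± 48.4 to 39.8 ± 3.69 CPM (-1.42, SE 0.28). The neural adhesion molecule ncam3 (-1.91, SE 0.22), the nucleoside diphosphate kinase nme2a (-2.26, SE 0.48), the amylase amy2al1 (-1.72, SE 0.25), the egg coat gene zp3e (-1.51, SE 0.30) and RRM2 (ENSDARG00000078069; -1.75, SE 0.48), a ribonucleotide reductase subunit, were each below the 1 year median in 7 of 7 fish. The remaining decreases were alpk2 (-3.93, SE 0.57), a kinase gene, CKMT2 (ENSDARG00000069615; -4.71, SE 1.29), the creatine kinase of muscle mitochondria, and the prolactin gene prl2 (-1.70, SE 0.39). Replicate 4 of the 1 year fish at 37.5 nM held 5.43 log2 CPM of CKMT2, against at most 1.53 in the other 8, and without it the log2 fold change was -2.21. CKMT2 lost its call in 6 of 16 fits with 1 library left out, and RRM2 in 8.

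Endothelial genes were lower as a list (0 higher, 3 lower of 44, 5 lower when adjusted over the list alone; median -0.18, camera adjusted p = 0.00045, but 0.632 with an estimated correlation). Those passing were tek, the junction gene CLDN5 (ENSDARG00000043716; -0.53, SE 0.15) and CTNND1 (-0.22, SE 0.06). Its score differed by -0.20 and -0.19 within the runs. Pituitary genes were lower too (2 of 12, 8 when adjusted over the list alone; camera adjusted p = 0.000684, but 0.171 with an estimated correlation). Of these prl2 and the secretogranin gene scg2b (-0.43, SE 0.09) passed, and SIX3 (ENSDARG00000058008) stood at -0.37 (SE 0.13). Its score was below the 1 year median in 7 of 7 fish and differed by -0.33 and -0.59 within the runs. Eye and pineal genes (0 of 23 past the test, 8 lower when adjusted over the list alone, median -1.48, camera adjusted p = 0.0041, but 0.695 with an estimated correlation) and skeletal muscle genes (0 of 25, 1 higher and 17 lower when adjusted over the list alone, median -2.48, camera adjusted p = 0.0208, but 0.768 with an estimated correlation) moved with single libraries. The photoreceptor genes GNAT1 (-4.21, SE 1.33) and ARR3 (ENSDARG00000056511; -3.19, SE 1.02), the melatonin enzyme gene aanat2 (-1.77, SE 0.57), and the muscle genes mybpc2b (-3.98, SE 1.19), MYL11 (ENSDARG00000002589; -0.42, SE 0.13) and atp2a1l (-4.46, SE 1.47) did not pass. Eye and pineal scores stood 3.26 and 2.53 log2 units above the median of all libraries in replicates 1 and 5 of the 1 year fish, and the muscle score 4.49 units above it in replicate 4. Without these 3 libraries and replicate 7 of the 3 year fish, whose skin score stood 1.75 units above the median, these 2 lists had camera adjusted p of 0.185 and 0.132. The 4 libraries were picked by an eye and pineal, muscle, pituitary or skin score over 1.5 log2 units above that median. That RNA of these tissues was carried over was inferred from such scores and not shown.

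In the neuronal lists most genes did not pass the test. Of all genes tested 7.79% changed in either direction, a share that the dopaminergic and progenitor lists exceeded and the synapse list did not. The share of lower genes among all tested (570 of 19887) was exceeded by each of these lists. In the dopaminergic and catecholamine list, 0 genes were higher and 3 lower of 25 (camera adjusted p = 0.0216, but 0.632 with an estimated correlation). These were the dopamine receptor drd4b (-0.76, SE 0.14), the transcription factor pitx3 (-0.72, SE 0.19) and OTP (ENSDARG00000014201; -0.37, SE 0.11). The synapse list had 3 of 47 lower (camera adjusted p = 0.0229, but 0.695 with an estimated correlation). Its lower genes were BDNF, the microtubule gene map2 (-0.18, SE 0.05) and GAD2, which makes the transmitter GABA (-0.39, SE 0.11). The synapse score differed by -0.12 and 0.06 within the runs. In the list of progenitors and immature neurons, 5 of 43 were lower and 1 higher (camera adjusted p = 0.0256, but 0.695 with an estimated correlation). SOX11 (ENSDARG00000077811; -0.45, SE 0.10), SOX4 (ENSDARG00000004588; -0.32, SE 0.08) and tmsb (-0.55, SE 0.15) passed, while the score differed by 0.10 in the first run and -0.25 in the second. When adjusted over the list alone, 3, 4 and 6 genes of these lists were lower and 1 gene of the progenitor list higher. Without the libraries with tissue scores over 1.5 log2 units above the median, the dopaminergic list had a camera adjusted p of 0.074 and the progenitor list of 0.104.

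Few genes of the respiratory chain, the target of rotenone, passed the test with age. Of 38 nuclear genes of complex I none passed and 35 had a negative log2 fold change (median -0.07, camera adjusted p = 0.00845, but 0.768 with an estimated correlation). Examples are NDUFB1 at -0.20 (SE 0.07), NDUFS7 at -0.13 (SE 0.06) and NDUFA3 at -0.16 (SE 0.08). Of 51 genes of complexes II to V, COX7C (-0.28, SE 0.07) and COX5A (-0.22, SE 0.06) were lower and cox7a1 stood at -1.88 (SE 0.60, not past the test), with a median of -0.13 (camera adjusted p = 5.67e-07, but 0.695 with an estimated correlation). None of the 13 mitochondrially encoded genes passed (median -0.15, camera adjusted p = 0.0229, but 0.768 with an estimated correlation). Among them MT-CO3 stood at -0.25 (SE 0.11), MT-CO2 at -0.21 (SE 0.10) and MT-CYB at -0.20 (SE 0.12). When adjusted over each list alone, 0 genes passed in these 3 lists. Scores differed by -0.15 and -0.02 within the runs for complex I, by -0.24 and -0.08 for complexes II to V, and by 0.01 and -0.24 for mitochondrially encoded genes.

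Among ribosomal protein genes RPL29 (-0.25, SE 0.06) and RPS7 (-0.20, SE 0.05) fell, and RPS6KA5, a kinase that the symbol pattern also takes, rose 1.17 (SE 0.32), while 91 of 94 did not pass (median -0.11, camera adjusted p = 5.67e-07, 0.722 with an estimated correlation; 1 lower when adjusted over the list alone). The heat shock list was higher (2 of 25, 4 when adjusted over the list alone; camera adjusted p = 0.0204, 0.695 with an estimated correlation) through the inducible chaperone gene hsp70l (2.36, SE 0.45) and its transcription factor hsf1 (0.33, SE 0.09), with CRYAB (ENSDARG00000101380) at 0.39 (SE 0.12). Its score differed by 0.35 and 0.21 within the runs.

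The DNA damage list did not move one way (camera adjusted p = 0.797), yet 4 of its 37 genes were higher and 1 lower, or 5 and 3 when adjusted over the list alone. CCNG1, a cyclin, rose 0.43 (SE 0.12), and fas, a death receptor, rose 1.56 (SE 0.26) from a low level. Glycolysis genes were likewise mixed (2 higher and 2 lower of 37, or 2 and 4 when adjusted over the list alone; camera adjusted p = 0.108), with the lactate transporter gene SLC16A3 (ENSDARG00000045051; -0.56, SE 0.14) and the glucose transporter gene slc2a3a (-0.20, SE 0.05) lower and slc2a3b (0.39, SE 0.11) higher. Of 38 clock genes PER2 (-0.34, SE 0.07) and cry3a (-0.15, SE 0.04) were lower and nr1d4b (0.51, SE 0.13) higher, the same count as when adjusted over the list alone (camera adjusted p = 0.0669, and 0.0328 with the run of title numbers as a covariate).

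Other lists did not pass by camera. Cell cycle genes counted 2 lower of 35 (3 when adjusted over the list alone), extracellular matrix 2 higher of 50 (2), proteasome 2 higher of 46 (2), integrated and mitochondrial stress 1 higher of 33 (1), skin and mucosa 1 higher of 25 (0), immediate early genes 1 higher of 33 (0) and cholesterol and lipid synthesis 1 lower of 36 (0). No gene passed in the lists of oxidative stress (29 genes), radial glia (28), oligodendrocytes (26), pericytes and smooth muscle (24) and red blood cells (17).

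**Figure D2:**
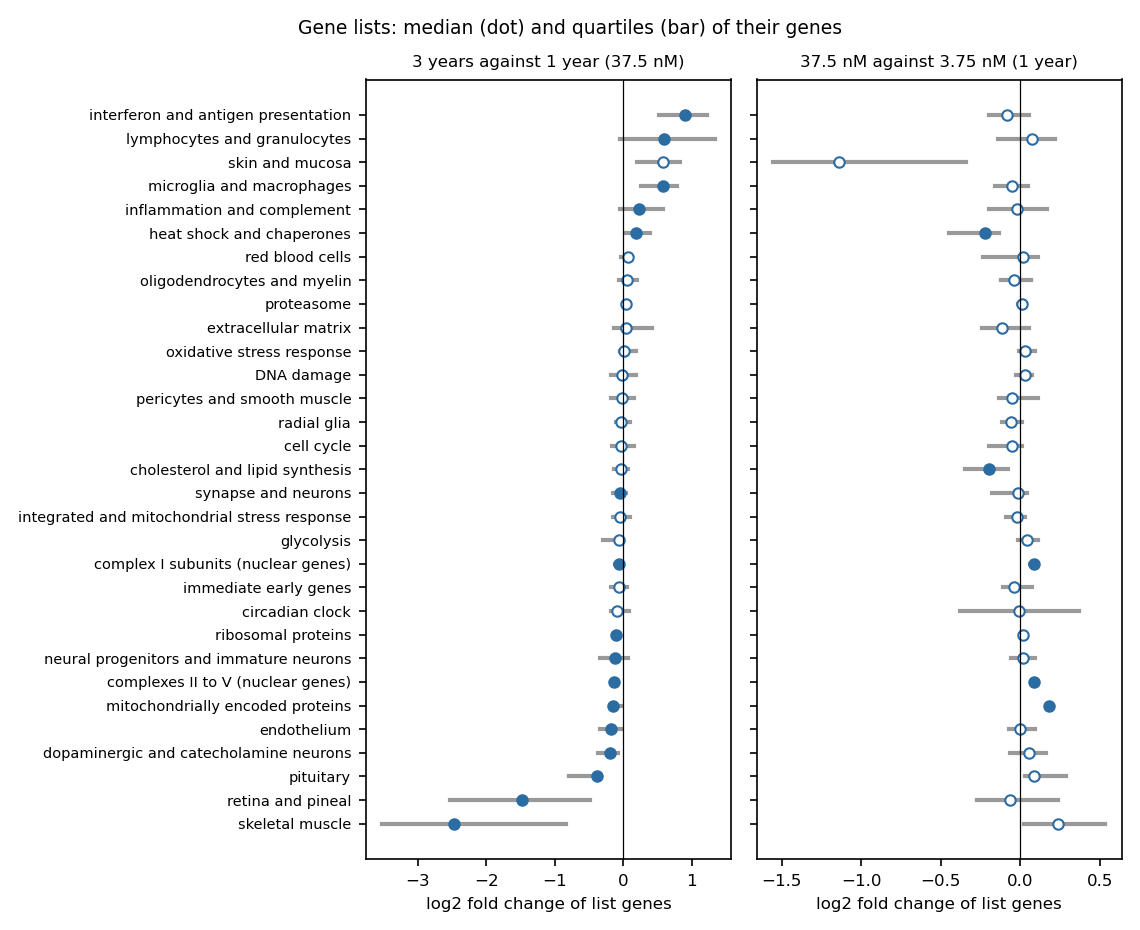
Median (dot) and quartiles (bar) of the log2 fold changes of the measured genes of each of 31 lists, for 3 years against 1 year at 37.5 nM (left) and for 37.5 nM against 3.75 nM at 1 year (right), with filled dots where camera's adjusted p with the preset correlation was under 0.05. The 3 immune cell and interferon lists stand at medians of 0.58 to 0.90 in the age comparison.

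Within the first run alone 16 genes passed (edgeR, 3 against 4 fish) and within the second 1065. No gene showed a group difference that differed between the runs at adjusted p under 0.05 (1534 at unadjusted p under 0.05). In the first run 1521 of 1524 genes of the full comparison had the same sign. The full comparison holds these same libraries, so this agreement is partly built in and is no replication. The count of 1549 was 2899 by DESeq2's Wald test, 738 without the 4 libraries with high tissue scores, 942 without replicate 4 and 944 without replicate 7 of the 3 year fish.

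At 1 year, 4 of the 10 genes that differed between fish at 37.5 nM and at 3.75 nM belong to the list of circadian clock genes. BMAL1 (ENSDARG00000006791), which drives the clock with CLOCK, rose from 59.7 ± 9.31 to 81.0 ± 5.26 CPM (log2 fold change 0.44, SE 0.08, adjusted p = 0.0379). The cryptochrome genes cry3b (0.48, SE 0.08, adjusted p = 0.0162) and cry4 (0.40, SE 0.07, adjusted p = 0.0472) rose with it. BHLHE41, a repressor of clock transcription, went from 108.7 ± 13.0 to 80.6 ± 7.43 CPM (-0.43, SE 0.07, adjusted p = 0.0162). Each was on its side of the 3.75 nM median in 9 of 9 fish at 37.5 nM. Outside the clock list, MXD3, a partner of MAX (0.62, SE 0.10), YPEL3 (0.32, SE 0.05) and the nociceptin precursor gene pnocb (0.52, SE 0.09) were higher.

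These were 7 of only 10 genes that passed by edgeR among 19691 tested, 7 higher and 3 lower, with 1821 at unadjusted p under 0.05. The other 3 carry clone names and fall outside the rule for named genes: si:ch211-278f21.5 (0.82, SE 0.12), zgc:194398 (-0.37, SE 0.06) and si:ch211-132b12.7 (-1.22, SE 0.22), chosen after their values were seen.

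Of 38 clock genes 3 were higher and 1 lower over all genes, and 11 higher and 6 lower when adjusted over the list alone. Members of this wider count, chosen after their values were seen, included the repressor genes PER3 (-1.19, SE 0.26), NR1D2 (-0.91, SE 0.18) and PER1 (ENSDARG00000012499; -0.82, SE 0.19), and nfil3-5 (0.96, SE 0.20). Against these repressors nr1d4b, of the same family as NR1D2, was higher (0.90, SE 0.22). Members went both ways, so camera found no shift (adjusted p = 0.21), while fry's test of change in either direction gave an adjusted p of 1.86e-05. Within the runs, BMAL1 differed by 0.55 and 0.36, cry3b by 0.48 and 0.51, cry4 by 0.45 and 0.38, and BHLHE41 by -0.43 and -0.41. With 1 of 19 libraries left out in turn, the call was lost in 15 fits for cry4, 14 for BMAL1, 11 for pnocb and 1 each for cry3b, BHLHE41, MXD3 and YPEL3.

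**Figure D3:**
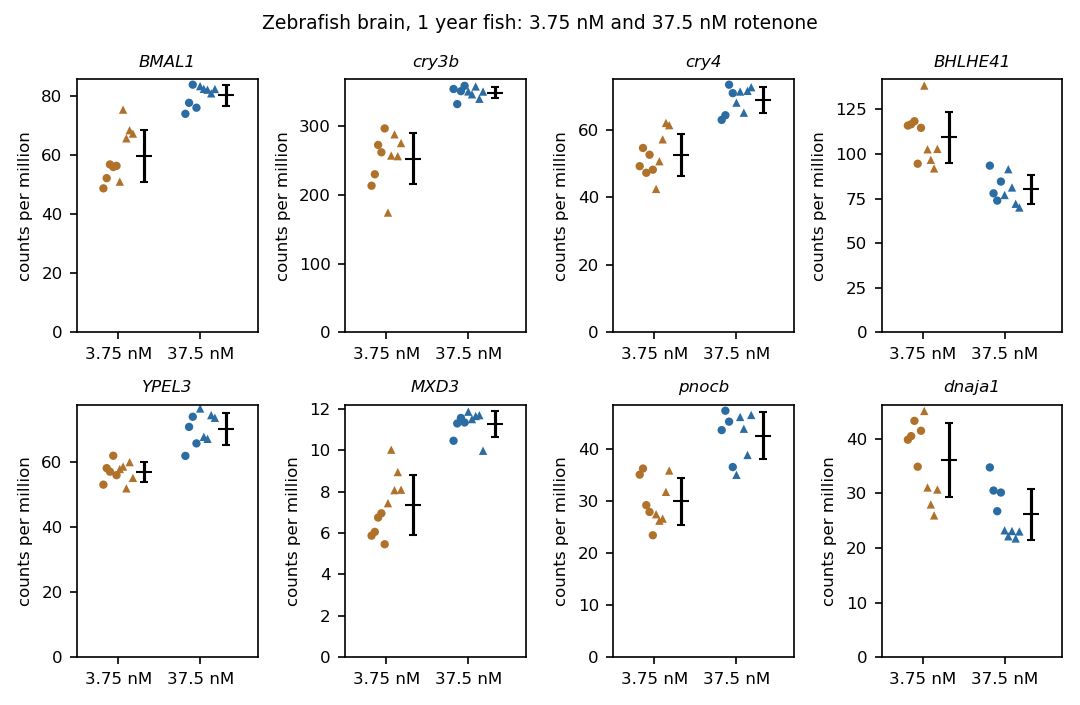
Counts per 1000000 of library total for 8 genes in each 1 year fish at 3.75 nM (n = 10) and 37.5 nM (n = 9), with circles for the first run of title numbers, triangles for the second, and mean ± SD beside the points. BMAL1 (ENSDARG00000006791), cry3b, cry4, YPEL3, MXD3 and pnocb lay higher at 37.5 nM and BHLHE41 lower, and the chaperone gene dnaja1 did not pass the test.

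Of 25 heat shock and chaperone genes none passed over all genes at 37.5 nM, 9 were lower when adjusted over the list alone, and the median was -0.22 (camera adjusted p = 4.17e-11, but 0.137 with an estimated correlation). The collagen chaperone gene SERPINH1 (ENSDARG00000019949) stood at -2.0 (SE 0.46), and the co-chaperone genes dnaja1 at -0.45 (SE 0.11; 35.8 ± 6.34 and 26.2 ± 4.19 CPM) and dnajb1a at -0.57 (SE 0.14), each below the 3.75 nM median in 9 of 9 fish. The list score was below the 3.75 nM median in 9 of 9 fish and differed by -0.36 and -0.27 within the runs. It averaged 4.565 at 3.75 nM, 4.235 in the 1 year fish at 37.5 nM and 4.501 in the 3 year fish. The middle group is also the reference of the age comparison. A shift of that group alone would give both this fall and the rise with age, so they are not separate results.

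No respiratory chain gene passed the test at 37.5 nM, also when adjusted over the list alone. All 38 complex I genes (median 0.09, camera adjusted p = 1.03e-06), 49 of 51 genes of complexes II to V (0.09, adjusted p = 1.23e-07) and all 13 mitochondrially encoded genes (0.18, adjusted p = 4.28e-08) had a positive log2 fold change. With an estimated correlation the adjusted p was 0.896 for each of these lists. Examples are NDUFB1 at 0.14 (SE 0.06), NDUFA1 at 0.09 (SE 0.06), COX5A at 0.16 (SE 0.08), UQCRC2 at 0.13 (SE 0.07), MT-CYB at 0.26 (SE 0.11) and MT-CO1 at 0.19 (SE 0.09). Cholesterol and lipid synthesis genes had a median of -0.20 (0 of 36 past the test, also when adjusted over the list alone; camera adjusted p = 4.28e-08, but 0.848 with an estimated correlation). The mevalonate pathway gene HMGCS1 stood at -0.50 (SE 0.17) and the squalene epoxidase gene SQLE (ENSDARG00000079946) at -0.72 (SE 0.25). Scores within the runs differed by 0.09 and 0.09 for complex I, 0.11 and 0.08 for complexes II to V, 0.21 and 0.15 for mitochondrially encoded genes, and -0.28 and -0.20 for cholesterol genes. Complex I scores averaged 5.985 at 3.75 nM, 6.069 in the 1 year fish at 37.5 nM and 5.994 at 3 years. In that order the means were 6.952, 7.035 and 6.88 for complexes II to V, and 12.058, 12.242 and 12.112 for mitochondrially encoded genes. The middle group is in both comparisons and stood highest in these lists. A shift of that group alone would give both this rise and the fall with age, so they are not separate results.

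No gene outside the clock list passed in the other 25 lists, and none of these lists passed by camera. Skin and mucosa genes had the widest shift among them (median -1.14, camera adjusted p = 0.21), with the score of replicate 4 at 3.75 nM 3.62 log2 units above the median of all libraries. When adjusted over the list alone, 2 endothelial genes, 1 pituitary gene and 1 inflammation gene were higher and 1 stress response gene lower.

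Within the first run 12 genes passed by edgeR and within the second 0 (2454 at unadjusted p under 0.05), with no gene whose difference differed between the runs at adjusted p under 0.05 (1452 at unadjusted p under 0.05). The count of 10 was 65 by DESeq2's Wald test, 24 with the run as a covariate and 2 without replicate 8 at 37.5 nM. Tissue scores over 1.5 log2 units above the median were found in 7 libraries, replicates 1, 3, 4 and 5 at 3.75 nM and 1, 4 and 5 at 37.5 nM. Without them the count was 0 (edgeR, 2087 at unadjusted p under 0.05). There each of the 7 named genes kept its sign, though in libraries that were part of the fit that called them.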

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

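Which values to test for single far-off libraries was chosen with the named genes and lists, and no explanation below was tested. Of 298 tests of a group, 33 had a library far from the others, where chance alone gives about 1 in 20.

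Among named genes in 1 year fish at 37.5 nM, the log2 CPM of replicate 4 stood above the others for atp1a1a.4 (0.91), CKMT2 (ENSDARG00000069615; 5.43), mybpc2b (5.36) and atp2a1l (7.90). Replicate 9 stood above for nme2a (3.49), replicate 1 above for fas (0.65) and replicate 2 below for zp3e (0.82). Among 3 year fish, replicate 5 stood below for btr23 (-0.47, others 2.54 to 4.07), SMAD1 (5.01) and CCNG1 (7.77), and above for CLDN5 (ENSDARG00000043716; 4.65) and aanat2 (2.16). Replicate 1 stood above for prl2 (3.70) and cox7a1 (2.96), and replicate 2 below for drd4b (0.54).

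Among list scores (mean log2 CPM) at 37.5 nM and 1 year, replicate 4 stood above the others for skeletal muscle (5.86) and glycolysis (6.98), replicate 1 above for lymphocytes and granulocytes (2.24), replicate 7 above for oligodendrocytes (6.27) and replicate 3 below for dopaminergic neurons (2.21). At 3 years, replicate 1 stood above for complex I (6.21) and complexes II to V (7.10), replicate 5 above for endothelium (4.21), replicate 6 above for extracellular matrix (4.48) and replicate 4 below for the proteasome (4.94, others 5.42 to 5.54). At 3.75 nM, replicate 4 stood above for skeletal muscle (5.03) and ribosomal proteins (7.64), replicate 8 above for radial glia (6.21) and endothelium (4.48), and replicate 6 below for the integrated and mitochondrial stress response (5.17).

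Replicate 3 of the 1 year fish at 37.5 nM had a count in about 23690 genes, fewer than the others. Replicate 8 at 3.75 nM had 13.7% of its counts in mitochondrially encoded genes (others 8.33% to 11%) and 15.05% in its 10 most abundant genes (others 9.70% to 12.3%).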

How the results depend on the processing

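The settings without carried-over tissue RNA, the ribosomal list without kinases and the test for a difference between runs were chosen only after results had been seen. Carried-over tissue RNA was inferred from a tissue score over 1.5 log2 units above the median of all libraries and was not shown. The age count of 1549 genes was 2899 by DESeq2's Wald test, 16 in the first run alone (2408 at unadjusted p under 0.05, edgeR), 308 and 296 with the deposited RPKM scores, 738 without the libraries with carried-over tissue RNA, and 942 to 2156 with 1 library left out, where leaving out 3 year replicate 4 (942) or 7 (944) took it down by more than 1.5 times. The first run alone and the fits with left-out libraries have fewer samples, yet the count rose to 2156 without 3 year replicate 1. The cause of the shifts was not tested. The count stayed within 1.5 times in the other settings (1065 to 1975), and all 1549 genes kept their sign by DESeq2 on the same libraries. Reversed values in the first run were s100s (-0.20) and LOXL2 (-0.32). The dose count of 10 genes was 65 by DESeq2's Wald test, 18 in a fit of all 26 libraries, 24 with the run as a covariate, 0 in the second run alone (2454 at unadjusted p under 0.05, edgeR), 0 without carried-over tissue RNA (2087 likewise, against 12 in the first run and 13 by limma voom), and 2 to 12 with 1 library left out. It was 6 without replicate 2, 3, 6 or 9 at 37.5 nM or replicate 3 or 4 at 3.75 nM, and 2 without replicate 8 at 37.5 nM. All 10 kept their sign in every setting, but each setting uses libraries of the fit that called them. The cause of the shifts in count was not tested. Of 16 lists called with age, 0 passed with an estimated correlation and 5 by fry, 17 (the clock list added) with the run as a covariate, and of 5 with dose, 0 and 1. Those passing by fry with age were the interferon, microglia, lymphocyte, inflammation and pituitary lists (adjusted p from 0.00124 to 0.0119). With dose it was the heat shock list (adjusted p by fry = 0.0424). Without carried-over tissue RNA, 15 and 7 passed: with age the retina, muscle, dopaminergic and progenitor lists were lost and the immediate early, clock and cholesterol lists gained, and with dose the ribosomal and proteasome lists gained. Of 76 named genes with age, 70 stayed on their side of the threshold with the run as a covariate, 67 by limma voom, 47 in the second run and 18 in the first. Named genes that did not pass the main test count here as staying when they fail again. In the first run 55 of the 76 lost their call and 2 reversed sign, and in the second run 28 lost it. In the smallest library 20.6 counts equal a CPM of 1, which limits genes under that level, cd8a and ifi44a6 among them.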

Other observations

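The gene groups of the next paragraph, and all tests of this part except the random splits, the neighbouring genes and the runs of title numbers (though not the library left out there), were chosen only after the results had been seen.

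Of 24 T cell genes 20 were higher in 3 year brains, 7 of 8 that the lymphocyte list also holds and 13 of 16 outside it. Among them were the chemokine receptor gene CXCR3 (2.28, SE 0.27), the kinase genes jak3 (1.75, SE 0.26) and lck (1.48, SE 0.32), the T cell receptor gene trbc1 (2.51, SE 0.42) and the helper cell gene cd4-1 (1.77, SE 0.36), while TCF7 and PRKCQ did not pass the test. This set holds genes picked because they were high, so its share is no test. Of the granzyme genes 4 of 4 rose (gzm3 by 2.66, SE 0.34), and of the immune-type receptor genes 3 of 3 (nitr2a by 2.36, SE 0.31). Chemokine genes counted 8 higher of 21 (ccl36.1 by 2.2, SE 0.27), PARP9 and PARP14 genes 3 of 3, btr genes 4 of 10, ifi44 genes 3 of 7, mhc1 genes 4 of 11, mhc2 genes 2 of 3, gbp genes 2 of 3, gig2 genes 2 of 4, galectin 9 genes 2 of 3 and chemokine receptor genes 4 of 12. In the largest family, finTRIM, 4 of 41 were higher, against 979 of 19887 among all genes tested. Interferon regulatory factor genes counted 6 higher of 10 (irf9 by 0.75, SE 0.11; irf1b by 0.60, SE 0.11).

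For the immune genes of 3 year brains, a lower share of neuronal RNA would raise other cell types alike. The microglia median of 0.58 stood 0.53 above the highest of the medians of radial glia (-0.03), oligodendrocytes (0.05), endothelium (-0.18) and pericytes (-0.03). A lower neuronal share alone would not give this gap, but a part of it in the rise is not excluded. Blood left in the brains would raise red cell genes, but the lymphocyte median stood 0.53 above the red cell median of 0.06. More immune cells or more active ones may both account for the rise, and age and line are not separable here.

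For the large age differences, RNA of eye, muscle, pituitary or skin carried into single libraries would vanish without the libraries with high scores for these tissues. Without 3 year replicate 7, 99% of the 404 higher genes kept over 50% of their log2 fold change. Without 1 year replicates 1, 4 and 5, 92.4% of the 66 lower genes did. The 4 and 5 genes no longer tested, CKMT2 (ENSDARG00000069615) among them, were counted as not kept, and all genes tested again kept it. These genes had been called with the same libraries included, which favours this outcome. Libraries with lower scores stayed in, among them 3 year replicate 5 with a skin score 1.33 log2 units above the median. Carried-over RNA is therefore not excluded. Haplotype differences between the fish lines might place large changes next to each other. There were 9 neighbouring pairs (cd22 with ncam3 and CASKIN2 with nme2a among them), against a median of 5 and a 95th percentile of 9 in random sets (1-sided permutation p = 0.0638). Both genes of each pair changed in the same direction. By the rule fixed beforehand, 9 pairs do not exceed the random sets. Only 69.6% of the genes could be placed, under a minimum of 80% that was not part of that rule. With so many genes not placed, the check is void and cannot tell. Of 100 splits of the libraries only 1, the labelled one, called as many genes, for age and for dose alike. The random splits were not balanced for the run of title numbers. The highest other split called 1115 genes with age and 5 with dose, and splitting by the run of title numbers called 1315 and 1861.

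For the clock genes of the dose comparison, brains taken at another clock phase would move the BMAL and CLOCK set against the PER and NR1D set. The means were 0.17 (11 genes, 7 higher) and -0.24 (18 genes, 13 lower), with a permutation p = 0.0345, but the sets were chosen after the calls, hold genes already called, leave out cry3b and cry4, and were permuted as if genes that move together were independent. This test is void, and a difference in the time of day, which the labels do not give, stays open. The clock index, the difference of these sets in each library, was higher at 37.5 nM by 0.52 in the first run and by 0.304 in the second. With 1 library left out in turn, the first run gave 0.482 to 0.595. The second gave 0.10 without replicate 6 at 3.75 nM (-0.87). A difference within a run cannot come from the run of title numbers, which argues against the run as its source in the first run. It may still come from the order of numbers within a run, where each group holds its own block. In the second run the size of the difference rests on that 1 library. An effect of concentration on the clock could give the same values and was not tested apart from time and table.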
